A study of Mus musculus with 12 samples.

How the data were processed

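RNA from the hippocampus and the prefrontal cortex of 3 male C57BL/6 mice given X-rays to the abdomen and of 3 mice without irradiation was sequenced, 1 library per region and mouse, 12 in all. Per the labels' protocols, RNA was extracted with Trizol and libraries were built with a directional (strand-marking) NEBNext Ultra II kit. All 12 libraries carry 1 batch label. The dose of 13 Gy is part of the irradiated libraries' names in the labels. The time after irradiation is not given in the sources used here.

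Each library came as a table with a gene symbol and 1 value per gene, deposited by the authors. Reads were aligned with TopHat to mm10, per the submitters' processing notes, without versions. The counting tool, the gene annotation and whether counting used the strand are not given in the sources used here. The tables name no unit. The deposited values were taken as FPKM (fragments per kilobase of transcript, relative to the library's mapped fragments), because they are not whole numbers, their sums differ between libraries, from 381417 to 435534, and the sum of value times transcript length in kilobases came to between 1.2 and 1.25 M (mega) in every library, near the 1 M that FPKM give. RPKM would look the same. FPKM are relative to each library's total, so a change in a few abundant genes moves all others, and genes that overlap on opposite strands share fragments if the strand was not used. Of the 23183 symbols, 22148 (95.54%) matched a GENCODE M21 gene, the mm10 annotation used here for positions, transcript lengths and overlaps.

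Read counts were not used here, so depth was estimated from the values. A single fragment is worth the same step of a gene's value in libraries of equal depth, and the steps of 2940 genes below 0.3 FPKM gave the relative depth of the libraries, which ran from 0.856 to 1.04. With 284 genes of a single transcript of at least 2000 bases, this came to about 15.5 to 18.7 M fragments per library. These estimates show similar depth in all groups and give no counting error per gene. 3607 genes were listed at 0 in all 12 libraries.

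The tests planned before the data were examined assumed counts. For normalized values the same plan named the test used here, limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the compared libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of genes below come from this test, and all tests are two-sided. A log2 difference on the log2(FPKM + 1) scale understates the change of genes near 1 FPKM. There were 4 comparisons: irradiated against control in hippocampus, the same in prefrontal cortex, the difference between these effects over all 12 libraries, and hippocampus against prefrontal cortex in control mice. The libraries fall into 4 groups of 3 by their titles, and the libraries of a group come from different mice. A fit of the mean of both regions per mouse was added after the data were seen.

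Gene groups came from 46 lists fixed before the data were examined. They hold markers of brain cell types, of tissue that dissection can bring along, of blood and of RNA quality, and genes of pathways that fit the brain and irradiation. A further list, counted among them, holds 15 single genes reported whatever their values. The others were tested with camera in limma at a preset inter-gene correlation of 0.01 where at least 5 members were tested, and with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes tested. It was run again with the correlation estimated from the data, which is large in lists whose members vary together between mice, and fry was run beside it. Over both regions and their difference, no list passed with an estimated correlation or with fry's directional test. Between the regions of control mice fry's directional test called 27 of 43 lists, while an estimated correlation called 0 even there.

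The genes named in the text follow a rule fixed before the data were examined, with mean FPKM in place of the count-based level it was written for. For each region and for the difference it takes up to 10 genes per direction past the threshold, at a mean of at least 1 FPKM and, within a region, with every irradiated library on the same side of every control library. Where fewer than 10 qualified, a direction was filled to 5 with the genes of smallest p under the same conditions of level and side. These are given as not passing. Genes with only a clone or predicted-gene name were not named, and a few genes that the rule takes are not reported here. Up to 4 members of each list described, those with the smallest p, and the 15 single genes were added. For the region comparison it takes the 5 largest differences in each direction at a mean of at least 10 FPKM.

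The titles number the mice, and same-numbered libraries of a treatment come from the same mouse. Deviations from the group means correlated between the 2 regions of a mouse at 0.17, 0.26 and 0.30 in irradiated mice 1 to 3 and at 0.29, -0.01 and 0.05 in control mice 1 to 3, and the 3 irradiated mice and control 1 matched best with their own number. Fits with the mouse as a block were therefore run for comparisons across regions. Irradiated and control mice with the same number are different animals.

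The gene test was first tested on simulated data at the spread of the real libraries, with 100 genes changed 2-fold and 100 changed 1.5-fold, drawn from genes of at least 5 FPKM. At 2-fold, 95 were called among 12947 genes in hippocampus, 94 among 12729 in prefrontal cortex, 91 among 12894 for the difference and 97 among 12923 for the regions. At 1.5-fold, 79, 67, 64 and 80 were called, with 10, 4, 6 and 10 false calls. These counts hold with 200 changed genes, where the adjustment is less strict than with few. Noise was drawn apart for each gene, while real genes vary together, so fewer changes may be found in the real libraries. Alternatives covered rescaling, low-value filters, thresholds, robust moderation, other pseudocounts (0.1 and 0.5), removal of each library's trend with transcript length, fits over all 12 libraries, blocks and leaving out each library. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.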

Results

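RNA of the hippocampus and of the prefrontal cortex was sequenced from 6 male C57BL/6 mice, an inbred laboratory strain. In 3 of them X-rays had been directed at the abdomen, with 13 Gy in the library names, as a model of lasting injury of the gut, and 3 were not irradiated. The brains were sampled in the chronic phase, at a time that is not given in the sources used here. The 12 libraries formed 4 groups of 3, each with 1 library per mouse. Between 12640 and 12967 genes reached at least 1 FPKM in a library. Estimated depth ran from about 15.5 M (mega) fragments in prefrontal cortex control 1 to about 18.7 M in prefrontal cortex control 3. The 10 most abundant genes held 3.73% to 5.79% of a library's sum. Levels below are means ± SD of FPKM (n = 3 mice per group), and log2 differences carry their SE. Gene positions are those of mm10.

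Hippocampus and prefrontal cortex of control mice were compared first, which also checked the region labels. C1ql2, a secreted protein of dentate granule cells (chromosome 1, 120340582 to 120343174), stood at 35.3 ± 3.47 FPKM in hippocampus and 0.688 ± 0.138 FPKM in prefrontal cortex, a log2 difference of 4.42 ± 0.10 (adjusted p = 6.38e-08). Fibcd1 and Spink8, markers of CA1 pyramidal cells, were higher in hippocampus by 3.30 and 3.72 on the log2 scale, and Homer3, a postsynaptic scaffold protein, by 2.45. Tbr1 and Foxp2, transcription factors of cortical projection neurons, were lower in hippocampus, with log2 differences of -1.57 and -2.30, and that of Lamp5, a membrane protein of cortical neurons, was -2.22. Of 24 genes of the hippocampal subfields, 18 were higher in hippocampus and 1 was lower, both over all genes tested and adjusted over the list alone (camera adjusted p = 1.9e-11). Of 22 genes of the cortical layers, 16 were lower and 3 higher over all genes, and 16 and 4 adjusted over the list alone (camera adjusted p = 1.65e-06). Each of these 2 list results had an adjusted p = 0.349 with an estimated correlation. Fry's directional test gave adjusted p = 0.000206 for the hippocampal subfields and 0.000518 for the cortical layers.

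Both dissections also carried transcripts of neighbouring tissue. All 21 tested genes of the choroid plexus, the epithelium that makes cerebrospinal fluid, were higher in hippocampus over all genes and adjusted over the list alone, with a median log2 difference of 3.39 (camera adjusted p = 2.57e-23, adjusted p = 0.349 with an estimated correlation). Ttr, the thyroid hormone carrier transthyretin (chromosome 18, 20665280 to 20674321), stood at 4577 ± 1016 FPKM in control hippocampus and 20.4 ± 32.7 FPKM in control prefrontal cortex, where control 3 alone reached 58.1 FPKM. The folate receptor Folr1, the ageing-related hormone co-receptor Kl, the BMP antagonist Sostdc1 and the potassium channel Kcnj13 were higher in hippocampus by 4.82, 4.40, 4.26 and 4 on the log2 scale. All 17 tested striatal genes were lower in hippocampus, over all genes and adjusted over the list alone, with a median of -2.74 (camera adjusted p = 7.59e-22, adjusted p = 0.349 with an estimated correlation). Penk, which encodes the opioid precursor proenkephalin, stood at 219 ± 22.6 FPKM in prefrontal cortex and 20.7 ± 1.68 FPKM in hippocampus. The adenosine receptor Adora2a (chromosome 10, 75316877 to 75334784) had a log2 difference of -4.33, the sodium channel subunit Scn4b of -3.83, the dopamine receptor Drd2 of -3.25 and the signalling regulator Rgs9 of -3.10. Lrrc17, a secreted leucine-rich repeat protein, and Dkkl1 followed with -3.67 and -3.41. All 12 tested genes of ependymal cilia and 21 of 24 myelin genes (22 adjusted over the list alone) were higher in hippocampus, with medians of 1.59 and 0.48 (camera adjusted p = 7.58e-10 and 2.58e-09, adjusted p = 0.349 and 0.4 with an estimated correlation). With fry's directional test the choroid plexus and striatal lists had adjusted p = 0.000518 and 0.000232, and the ependymal and myelin lists 0.000617 and 0.00624. In total limma called 3922 of 12923 genes, 2030 higher in hippocampus and 1892 higher in prefrontal cortex. The libraries of the regions did not overlap for 45.7% of genes, against 10% by chance.

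The main question of the design was which genes differ in the brain long after the abdomen was irradiated. In hippocampus, Vegfa, the growth factor that drives vessel growth (chromosome 17, 46016993 to 46032369), stood at 21.4 ± 1.74 FPKM in irradiated and 13.9 ± 0.82 FPKM in control mice, a log2 difference of 0.59 ± 0.07 (adjusted p = 0.128). Lrg1, an acute-phase glycoprotein also made by endothelium (chromosome 17, 56119678 to 56122001), stood at 2.26 ± 0.36 and 0.517 ± 0.208 FPKM (log2 difference 1.11 ± 0.14, adjusted p = 0.128). Acer2, a ceramidase of the Golgi (chromosome 4, 86874396 to 86934822), stood at 2.99 ± 0.457 against 0.944 ± 0.066 FPKM, and Crabp2, a carrier of retinoic acid (chromosome 3, 87948666 to 87953376), at 4.05 ± 0.51 against 1.44 ± 0.248 FPKM. Ctgf, a secreted matrix protein induced by TGF-beta, stood at 8.38 ± 1.26 against 3.54 ± 0.489 FPKM. The log2 differences of Acer2, Crabp2 and Ctgf were 1.03 ± 0.11, 1.05 ± 0.12 and 1.04 ± 0.12, each with an adjusted p of 0.0971. On the lower side, Ninj2, an adhesion protein of injured nerve, stood at 1.89 ± 0.00414 against 3.44 ± 0.249 FPKM (log2 difference -0.62 ± 0.08, adjusted p = 0.148). Chchd1 and Mrpl34, proteins of the mitochondrial ribosome, had log2 differences of -0.41 and -0.31, the apoptosis regulator Siva1 of -0.47 and the antisense RNA Med9os of -0.87, with adjusted p between 0.148 and 0.417. In each of these 10 genes every irradiated library lay on the same side of every control library, because the naming rule took only such genes.

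None of the 12947 hippocampal genes passed limma's test after adjustment. Unadjusted p-values under 0.05 were found for 1361 genes, against 647 expected by chance, and libraries of the groups did not overlap for 2017 genes (15.6%, against 10% by chance), 960 higher and 1057 lower in irradiated mice. The count of 1361 depended on single libraries. It was 580 without control hippocampus 1, against 648 expected, and 1998 without control hippocampus 3. Acer2, Ctgf, Crabp2 and Lrg1 passed when values were rescaled to equal totals (adjusted p = 0.0472 for each), the first 3 also with robust moderation (adjusted p = 0.0496), and Vegfa passed in 1 fit over all 12 libraries (adjusted p = 0.0412). A single gene passed without irradiated hippocampus 1, the small nucleolar RNA Snora30, and a single gene without control hippocampus 3, the nuclear envelope gene Syne1, both named after their values were seen.

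Vascular genes leaned higher in the irradiated hippocampus. Of 24 endothelial and blood-brain barrier genes, 20 had positive differences, and 11 were higher adjusted over the list alone, against 0 over all genes tested, with a median log2 difference of 0.39 (camera adjusted p = 6.94e-11, adjusted p = 0.561 with an estimated correlation). Ly6a and Ly6c1, closely related surface proteins of brain endothelium, stood at 18.3 ± 3.19 against 8.43 ± 1.74 FPKM and at 25.9 ± 4.78 against 11.8 ± 3.06 FPKM. The adhesion molecule Pecam1 stood at 4.29 ± 0.603 against 2.36 ± 0.591 FPKM, the TGF-beta co-receptor Eng at 4.09 ± 0.431 against 2.5 ± 0.404 FPKM and the tight junction protein Cldn5 at 14 ± 2.58 against 8.66 ± 1.83 FPKM. All 13 genes of pericytes and smooth muscle had positive differences, 3 higher adjusted over the list alone and 0 over all genes, with a median of 0.31 that was 0.16 without control hippocampus 1 (camera adjusted p = 6.75e-06, adjusted p = 0.561 with an estimated correlation). Among them Vtn, the matrix protein vitronectin, stood at 42.4 ± 3.3 against 26.5 ± 4.38 FPKM, the receptor Notch3 at 1.84 ± 0.126 against 1.13 ± 0.122 FPKM and the potassium channel subunit Abcc9 at 1.45 ± 0.162 against 0.897 ± 0.0899 FPKM. Of 19 genes of meningeal and perivascular fibroblasts, 15 had positive differences, 6 higher adjusted over the list alone and 0 over all genes, with a median of 0.43 that was 0.25 without control hippocampus 1 (camera adjusted p = 9.21e-07, adjusted p = 0.561 with an estimated correlation). Col1a1, a chain of type I collagen, stood at 1.91 ± 0.0682 against 0.941 ± 0.414 FPKM, Fn1, which encodes fibronectin, at 7.07 ± 0.903 against 3.41 ± 1.7 FPKM and Bgn, a matrix proteoglycan, at 7.68 ± 0.612 against 4.98 ± 1.58 FPKM.

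**Figure D1:**
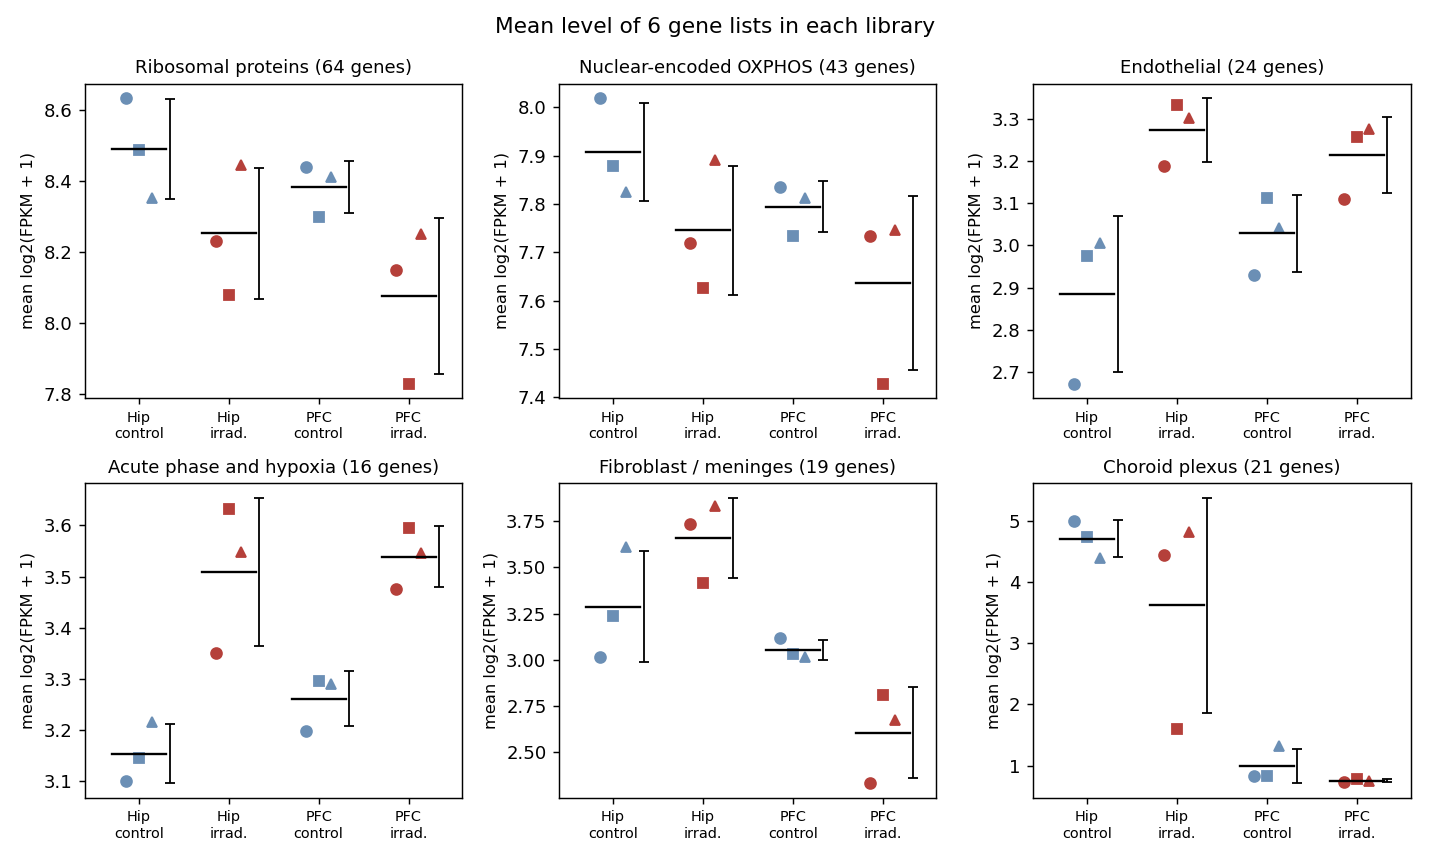
Mean log2(FPKM + 1) of the tested members of 6 gene lists in each library (circle, square and triangle for mice 1, 2 and 3, blue for control and red for irradiated, line and bar for mean and SD, n = 3). Ribosomal protein and fibroblast genes lie lower in every irradiated than in every control library of prefrontal cortex. In hippocampus ribosomal protein and oxidative phosphorylation genes of irradiated 3 and fibroblast genes of irradiated 2 lie within the range of the controls, and irradiated hippocampus 2 stands apart in choroid plexus genes, with y axes that do not start at 0.

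Genes of the acute phase and of hypoxia leaned the same way in hippocampus. Of 16 tested, 14 had positive differences. Adjusted over the list alone, 7 were higher and 1 was lower, against 0 over all genes (camera adjusted p = 6.75e-06, adjusted p = 0.561 with an estimated correlation). The median was 0.17 and the mean 0.36. The median was 0.09 without irradiated hippocampus 2, 0.08 without control hippocampus 1, 0.26 without control hippocampus 3 and 0.11 with no filter on low values. Besides Vegfa and Lrg1 the list holds Lcn2, an iron-scavenging acute-phase protein (chromosome 2, 32384633 to 32388252), listed at 1.09, 7.10 and 2.73 FPKM in irradiated mice 1, 2 and 3 and at 0.237, 0.0783 and 0.0858 FPKM in control mice (log2 difference 1.82 ± 0.41, adjusted p = 0.419). It also holds P4ha1, a collagen prolyl hydroxylase induced by low oxygen, at 13.3 ± 0.47 against 10.7 ± 0.78 FPKM. Of 22 genes that respond to glucocorticoids, 19 had positive differences and 0 passed over all genes or adjusted over the list alone (4 higher at an unadjusted p under 0.05), with a median of 0.19 that was 0.10 without irradiated hippocampus 3 (camera adjusted p = 0.000139, adjusted p = 0.561 with an estimated correlation). Klf9, a transcription factor of that response, stood at 56.9 ± 5.59 against 47.1 ± 5.12 FPKM, and Tsc22d3, an anti-inflammatory mediator, at 41.4 ± 10.1 against 30.3 ± 3.39 FPKM. Of 21 genes of the cortical layers, 19 had positive differences, 2 higher adjusted over the list alone and 0 over all genes (median 0.13, or 0.21 with values rescaled to equal totals, camera adjusted p = 7.24e-06, adjusted p = 0.561 with an estimated correlation). Tbr1 stood at 17.4 ± 1.71 against 13.4 ± 0.883 FPKM. The share of a prefrontal cortex profile, estimated from 189 genes higher in control prefrontal cortex, was 7.42%, 6.92% and 2.19% in irradiated hippocampus 1, 2 and 3 and -2.79%, 5.08% and -2.92% in control hippocampus 1, 2 and 3.

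Genes of protein synthesis and respiration leaned lower in the irradiated hippocampus. Of 64 ribosomal protein genes, 63 had negative differences and 0 passed in limma over all genes or adjusted over the list alone (23 lower at an unadjusted p under 0.05), with a median of -0.24 (camera adjusted p = 2.91e-17, adjusted p = 0.561 with an estimated correlation). The mean level of the list in irradiated hippocampus 3 lay within the range of the control libraries. Without irradiated hippocampus 2 the median was -0.15, with equal totals -0.15 and with the transcript length trend removed -0.11. Rps12 stood at 529 ± 83.9 against 673 ± 55.7 FPKM, and Rpl18 at 234 ± 28.3 against 285 ± 22.9 FPKM. Of 43 nuclear genes of oxidative phosphorylation, 42 had negative differences and 0 passed over all genes or adjusted over the list alone (10 lower at an unadjusted p under 0.05), with a median of -0.17 (camera adjusted p = 2.11e-08, adjusted p = 0.587 with an estimated correlation). That median was -0.11 without irradiated hippocampus 2, -0.12 without control hippocampus 1, -0.09 with equal totals and -0.04 with the length trend removed. Cox7a2, a subunit of cytochrome c oxidase, stood at 173 ± 21.7 against 216 ± 20.5 FPKM, and Ndufa1, a subunit of complex I, at 151 ± 25.2 against 198 ± 28.5 FPKM.

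Genes of homeostatic microglia and myelin also leaned lower. Of 22 genes of homeostatic microglia, 20 had negative differences, 3 lower adjusted over the list alone and 0 over all genes (median -0.12, camera adjusted p = 1.37e-05, adjusted p = 0.561 with an estimated correlation). The lipid receptor Trem2 stood at 11.3 ± 0.841 against 15.1 ± 0.801 FPKM, the actin-binding microglial marker Aif1 at 6.01 ± 0.526 against 8.65 ± 0.995 FPKM and the fractalkine receptor Cx3cr1 at 12.9 ± 0.324 against 15 ± 0.523 FPKM. With equal totals the median of this list was -0.04, and with the length trend removed -0.08. Of 24 myelin genes, 21 had negative differences and 0 passed over all genes or adjusted over the list alone, with 7 lower at an unadjusted p under 0.05 (median -0.18, or -0.10 with equal totals, camera adjusted p = 3.98e-05, adjusted p = 0.561 with an estimated correlation). Mbp, myelin basic protein, stood at 1271 ± 75.4 against 1580 ± 183 FPKM. All 21 choroid plexus genes had negative differences, with 0 past an unadjusted p of 0.05 or adjusted over the list alone and a median of -1.08 (camera adjusted p = 0.000115, adjusted p = 0.599 with an estimated correlation). That median was -0.09 without irradiated hippocampus 2, where the call was lost (camera adjusted p = 0.44). Ttr was listed at 2974, 52.1 and 4453 FPKM in irradiated mice 1, 2 and 3 and at 5625, 4509 and 3596 FPKM in control mice. All 14 genes of ependymal cilia had negative differences, 2 lower adjusted over the list alone and 0 over all genes (median -0.41, or -0.14 without irradiated hippocampus 2, camera adjusted p = 0.000117, adjusted p = 0.586 with an estimated correlation). In all, camera called 26 of 42 lists in hippocampus, 17 higher and 9 lower.

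Lists tied to radiation damage and neurogenesis gave no call in hippocampus. Of 22 genes of the p53 and DNA damage response, 11 had positive and 11 negative differences, 0 past the threshold over all genes or adjusted over the list alone and 1 at an unadjusted p under 0.05 (median 0, mean -0.02, camera direction higher, camera adjusted p = 0.745). Cdkn1a, the p53 target that arrests the cell cycle, stood at 4.29 ± 1.21 against 3.16 ± 0.132 FPKM. Of 22 genes of dentate neurogenesis, 2 were lower adjusted over the list alone and 0 over all genes (median -0.03, camera adjusted p = 0.435). These 2 were Fabp7, a fatty acid carrier of radial glia, at 31.5 ± 8.62 against 49.3 ± 3.88 FPKM, and Sox2, a stem cell transcription factor, at 25 ± 1.64 against 30.4 ± 1.18 FPKM. Dcx, a marker of young neurons, stood at 2.13 ± 0.362 against 1.94 ± 0.19 FPKM. The neurotrophin Bdnf stood at 10.1 ± 0.611 against 9.73 ± 0.494 FPKM, the astrocyte filament gene Gfap at 157 ± 21.4 against 193 ± 19.4 FPKM, the immediate early gene Fos at 6.31 ± 1.15 against 5.64 ± 1.43 FPKM, the stress response gene Fkbp5 at 18 ± 2.33 against 15.8 ± 1.5 FPKM and the complement gene C3 at 0.88 ± 0.058 against 1.07 ± 0.106 FPKM. The cytokine genes Tnf, Il1b, Il6 and Ccl2 had means below 1 FPKM in every group of both regions and were not tested. Of 20 other cytokine, chemokine and NF-kB genes, 14 had positive differences in hippocampus, 1 higher adjusted over the list alone and 0 over all genes (median 0.09, camera adjusted p = 0.031, adjusted p = 0.561 with an estimated correlation). That call was lost without control hippocampus 1 (median 0.06, camera adjusted p = 0.0504), control 2 (0.07, 0.151), irradiated 2 (0.08, 0.185) or irradiated 3 (0.08, 0.136) and with equal totals (0.15, 0.127), and the median was 0.06 with no filter on low values. In prefrontal cortex the list was not called (median 0.01, mean 0.10, camera adjusted p = 0.106). Lcn2 is on this list and also on the acute phase, glucocorticoid and reactive astrocyte lists, so the results of these lists are not independent.

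In prefrontal cortex, Vegfa stood at 22.6 ± 1.23 FPKM in irradiated and 15.8 ± 1.05 FPKM in control mice, a log2 difference of 0.49 ± 0.08 (adjusted p = 0.145). Bhlhe40, a transcription factor of the clock and of hypoxia, stood at 56.6 ± 4.91 against 39.3 ± 3.03 FPKM, Galnt9, an enzyme of O-glycosylation, at 25.9 ± 0.746 against 19.4 ± 0.94 FPKM and Klf2, a transcription factor of endothelium under flow, at 5.58 ± 0.736 against 3.37 ± 0.519 FPKM, with adjusted p of 0.177, 0.18 and 0.325. Omd, the matrix protein osteomodulin (chromosome 13, 49582462 to 49592822), stood at 2.01 ± 0.0492 against 3.84 ± 0.305 FPKM (log2 difference -0.69 ± 0.09, adjusted p = 0.0946). Rmrp, the RNA of the endonuclease RNase MRP, stood at 12.2 ± 2.79 against 31.4 ± 6.01 FPKM (log2 difference -1.31 ± 0.18, adjusted p = 0.0946), and its exon shares 124 bases with the opposite-strand gene Ccdc107. Rps28, a protein of the small ribosomal subunit (chromosome 17, 33819027 to 33824562), stood at 352 ± 33.4 against 547 ± 16 FPKM (log2 difference -0.64 ± 0.09, adjusted p = 0.0946), and shares 88 exon bases with the opposite-strand gene Kank3. The growth factor Mdk stood at 10.2 ± 0.307 against 14.5 ± 0.632 FPKM and Ass1, an enzyme of arginine synthesis, at 23.2 ± 1.26 against 34.1 ± 2.91 FPKM, each with an adjusted p of 0.143.

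Limma called 1 of 12729 genes in prefrontal cortex, and 920 had an unadjusted p under 0.05, against 636 expected by chance. The count of 920 became 671 without control prefrontal cortex 3, against 635 expected, and 1150 without control prefrontal cortex 1. The called gene was Snora81, a small nucleolar RNA of 178 bases (chromosome 16, 23110756 to 23110933), listed at 11.5, 13.6 and 16.1 FPKM in irradiated mice 1, 2 and 3 and at 0 in all 3 control mice (adjusted p = 9.47e-07). In hippocampus it was listed at 9.59, 6.91 and 0 FPKM in irradiated and 0, 7.36 and 0 FPKM in control mice. All of its bases lie within annotated exons of Eif4a2 on the same strand, so its value is uncertain, and the call was lost in 1 fit over all 12 libraries (adjusted p = 0.242). The libraries of the groups did not overlap for 1743 genes (13.7%, against 10% by chance). Without irradiated prefrontal cortex 1, 3 genes passed, among them Vwf, the clotting factor von Willebrand factor, at 2.61 ± 1.09 against 1.04 ± 0.0748 FPKM in all libraries. Without irradiated 2, 2 genes passed, and without control 1, 4 genes.

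**Figure D2:**
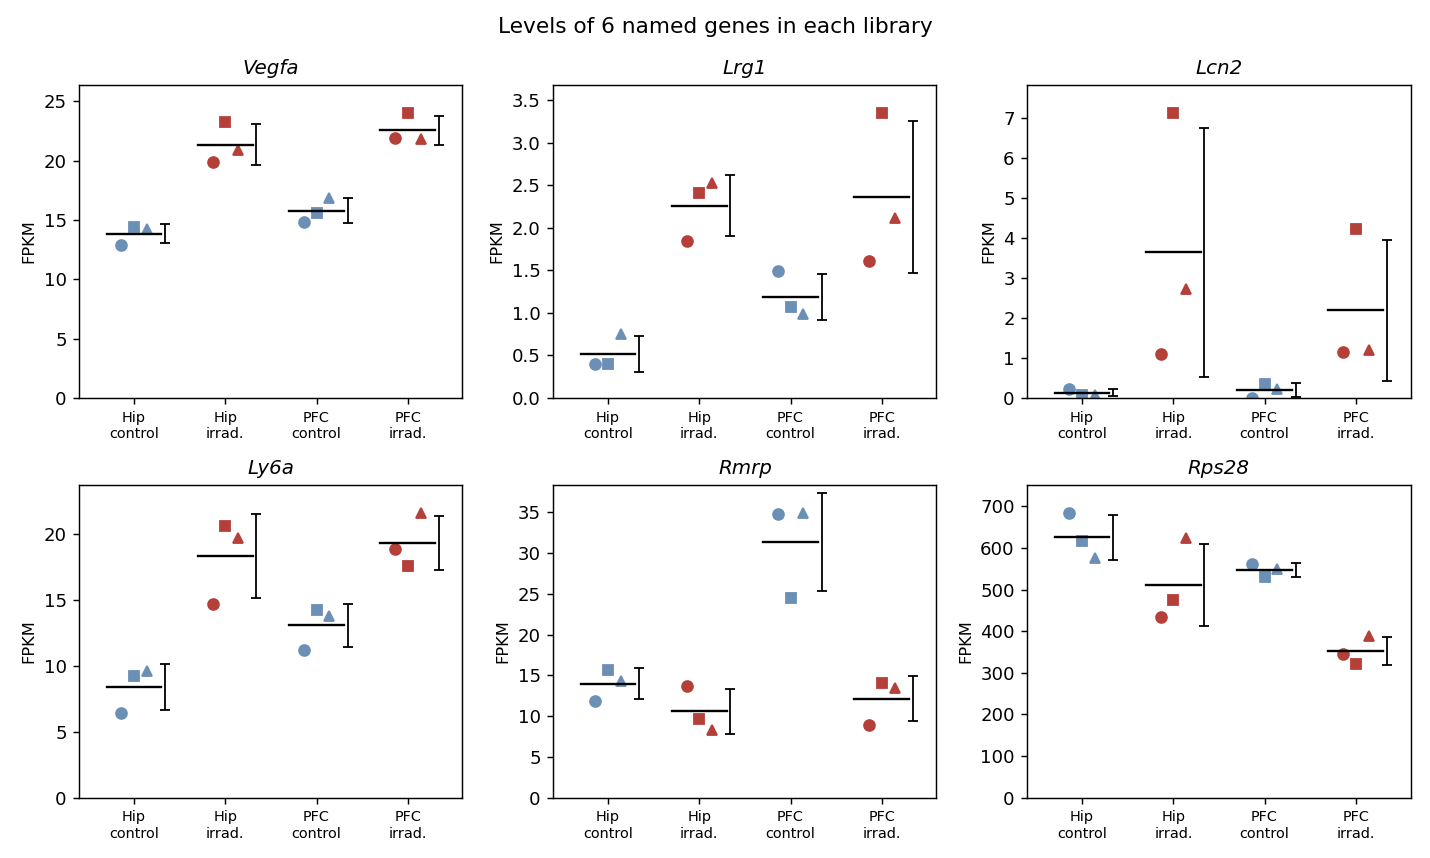
FPKM of Vegfa, Lrg1, Lcn2, Ly6a, Rmrp and Rps28 in each library, on y axes that start at 0 (circle, square and triangle for mice 1, 2 and 3, blue for control and red for irradiated, line and bar for mean and SD, n = 3). Every irradiated library lies above every control library of its region for Vegfa, Lrg1, Lcn2 and Ly6a, and the prefrontal cortex libraries of irradiated mice lie below their controls for Rmrp and Rps28.

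Ribosomal protein genes showed the largest list difference in prefrontal cortex by camera's p. Of 64, 63 had negative differences, and 32 were lower adjusted over the list alone against 0 over all genes, with a median of -0.31 (camera adjusted p = 2.54e-32, adjusted p = 0.329 with an estimated correlation). The median was -0.18 without irradiated prefrontal cortex 2 and -0.19 with the length trend removed. Rpl28 stood at 492 ± 43 against 730 ± 48.1 FPKM and Rpl17 at 382 ± 31.8 against 513 ± 30.7 FPKM. Of 43 nuclear genes of oxidative phosphorylation, 40 had negative differences and 4 were lower adjusted over the list alone against 0 over all genes (median -0.13, camera adjusted p = 1.75e-08, adjusted p = 0.42 with an estimated correlation). That median was -0.22 without irradiated prefrontal cortex 1, -0.03 without irradiated 2, -0.22 without irradiated 3, -0.06 with equal totals and -0.05 with the length trend removed. Cox8a, a subunit of cytochrome c oxidase, stood at 779 ± 30.6 against 1004 ± 13.3 FPKM, and Atp5j, a subunit of ATP synthase, at 195 ± 13.4 against 260 ± 16.7 FPKM.

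Fibroblast genes, markers of tissue that dissection can bring along, leaned lower in prefrontal cortex. All 18 tested genes of meningeal and perivascular fibroblasts had negative differences, 11 lower adjusted over the list alone and 0 over all genes, with a median of -0.48 (camera adjusted p = 8.99e-14, adjusted p = 0.329 with an estimated correlation). The secreted protein Serpinf1 stood at 3.54 ± 0.631 against 5.71 ± 0.527 FPKM, the GABA transporter Slc6a13 at 2.04 ± 0.613 against 3.95 ± 0.916 FPKM and the organic anion transporter Slc22a6 at 0.807 ± 0.31 against 1.9 ± 0.654 FPKM. Endothelial and stress genes leaned higher. Of 15 acute phase and hypoxia genes, 13 had positive differences and 5 were higher adjusted over the list alone against 0 over all genes (median 0.21, camera adjusted p = 3.41e-08, adjusted p = 0.178 with an estimated correlation). Lrg1 stood at 2.36 ± 0.893 against 1.19 ± 0.273 FPKM and P4ha1 at 12.1 ± 0.962 against 8.9 ± 0.343 FPKM, and Lcn2 was listed at 1.15, 4.23 and 1.2 FPKM in irradiated and 0, 0.350 and 0.231 FPKM in control mice. Of 24 endothelial genes, 23 had positive differences and 3 were higher adjusted over the list alone against 0 over all genes (camera adjusted p = 1.75e-06, adjusted p = 0.329 with an estimated correlation). Their median was 0.11, or 0.20 without irradiated prefrontal cortex 1, 0.18 without control 2 and 0.17 with equal totals. Ly6a stood at 19.3 ± 2.05 against 13.1 ± 1.64 FPKM and Cldn5 at 17.1 ± 1.38 against 14.9 ± 0.914 FPKM. The list of pericytes and smooth muscle was not called (9 of 13 genes with positive differences, median 0.02, camera adjusted p = 0.825). Of 22 glucocorticoid response genes, 17 had positive differences and 1, Lcn2, was higher adjusted over the list alone, against 0 over all genes (median 0.22, or 0.11 without irradiated 3, camera adjusted p = 1.98e-05, adjusted p = 0.329 with an estimated correlation).

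The lists of myelin, activated microglia and dentate neurogenesis leaned lower in prefrontal cortex. Of 24 myelin genes, 19 had negative differences, 1 lower adjusted over the list alone and 0 over all genes (median -0.12, or -0.08 without irradiated prefrontal cortex 2 and -0.05 with equal totals, camera adjusted p = 0.000109, adjusted p = 0.329 with an estimated correlation). That gene was Gjb1, the gap junction protein of myelinating cells, at 6.9 ± 0.413 against 9.43 ± 0.99 FPKM. Of 15 genes of activated microglia, 11 had negative differences, 2 lower adjusted over the list alone and 0 over all genes (median -0.16, or -0.09 without control 3, -0.10 with equal totals and -0.09 with the length trend removed, camera adjusted p = 0.00294, adjusted p = 0.329 with an estimated correlation). These were the lipid carrier Apoe, at 1318 ± 98.9 against 1800 ± 181 FPKM, and the matrix protein Spp1, at 3.24 ± 0.229 against 4.87 ± 0.862 FPKM. In hippocampus Apoe stood at 1923 ± 264 against 2316 ± 158 FPKM and Spp1 at 8.44 ± 2.05 against 4.61 ± 2.43 FPKM. The cells that carried these differences were not identified. The astrocyte list was called lower in prefrontal cortex too (median -0.08, camera adjusted p = 0.00486, adjusted p = 0.329 with an estimated correlation). Of 21 neurogenesis genes, 16 had negative differences, 3 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00441, adjusted p = 0.329 with an estimated correlation). Their median was -0.07, with -0.12 without irradiated 2, -0.05 without control 2, -0.11 without control 3 and -0.01 with equal totals. Fabp7 stood at 17.6 ± 5.86 against 30.3 ± 1.65 FPKM, the Notch effector Hes5 at 11.3 ± 2.67 against 16.8 ± 1.71 FPKM and the calcium-binding protein Calb2 at 9.05 ± 3.6 against 15.7 ± 2.76 FPKM. That list was drawn up for the dentate gyrus, so its members need not measure neurogenesis in prefrontal cortex. Calb2 is also on the olfactory bulb list, which was called lower too. There 5 of 6 genes had negative differences (median -0.30, camera adjusted p = 0.00223, adjusted p = 0.329 with an estimated correlation). The p53 list gave no call (22 genes, median 0.02, camera adjusted p = 0.425, 0 genes past the threshold over all genes or adjusted over the list alone, 1 at an unadjusted p under 0.05). Cdkn1a stood at 9.23 ± 1.25 against 7.75 ± 0.164 FPKM, Gfap at 35.4 ± 10.4 against 40.4 ± 1.59 FPKM, Aif1 at 7.23 ± 0.211 against 7.49 ± 1.2 FPKM, Bdnf at 5.76 ± 0.478 against 5.37 ± 0.265 FPKM, Fos at 14.2 ± 2.02 against 12.4 ± 1.63 FPKM, Dcx at 3.55 ± 0.213 against 3.7 ± 0.223 FPKM, Fkbp5 at 9.73 ± 0.71 against 9.05 ± 1.07 FPKM and C3 at 0.259 ± 0.027 against 0.155 ± 0.033 FPKM. Camera called 25 of 43 lists in prefrontal cortex, 8 higher and 17 lower, and 16 without control 3. The lower ones include hypothalamic neuropeptides (7 of 8 genes negative, median -0.33, camera adjusted p = 0.0454, adjusted p = 0.467 with an estimated correlation). Of that list, Oxt was listed at 0.535, 0.344 and 22.3 FPKM in control 1, 2 and 3, and Avp at 0.988, 0.956 and 11.3 FPKM. Neighbouring tissue in control 3 was not tested as a source of the lower calls.

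Whether irradiation went with different changes in the 2 regions was tested as the difference between the regional effects. Fibroblast genes, markers of tissue that dissection can bring along, had the smallest camera p. Of 19 tested, 17 had a more positive difference in hippocampus than in prefrontal cortex, 14 adjusted over the list alone and 0 over all genes, with a median of 0.80 (camera adjusted p = 4.09e-24, adjusted p = 0.209 with an estimated correlation). Slc6a13 stood at 5.1 ± 0.349 against 2.39 ± 1.45 FPKM in hippocampus, opposite to its order in prefrontal cortex, with a difference of 1.64 ± 0.34 on the log2 scale (adjusted p = 0.844). Col1a1 in prefrontal cortex stood at 0.96 ± 0.136 against 1.43 ± 0.322 FPKM, and its difference between regions was 0.91 ± 0.20 (adjusted p = 0.947). The ocular and meningeal protein gene Myoc stood at 15.7 ± 1.7 against 13.4 ± 2.52 FPKM in hippocampus and 6.59 ± 0.972 against 11.6 ± 1.67 FPKM in prefrontal cortex (difference 0.96 ± 0.20, adjusted p = 0.844). Crabp2 stood at 1.73 ± 0.811 against 2.98 ± 0.281 FPKM in prefrontal cortex, and its difference between regions was 1.64 ± 0.24 (adjusted p = 0.21). Omd and Mdk had differences of 0.79 and 0.57, and the calcium channel regulator Fkbp1b and Galnt9 of -0.41 and -0.38, with adjusted p between 0.844 and 0.947. The RNA polymerase subunit gene Polr3k, the mitochondrial ribosomal gene Mrps18b and Uxs1, an enzyme of glycan synthesis, followed with -0.34, -0.37 and -0.33.

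No gene of 12894 passed limma's test of the difference, with or without the mouse as a block. Unadjusted p-values under 0.05 were found for 422 genes without the block and 681 with it, against 645 expected by chance. Leaving out libraries, 1 gene passed without irradiated hippocampus 1 (Snora30), 2 without control hippocampus 3 (Syne1 and Slc6a13, the latter with an adjusted p of 0.0287), 1 without irradiated prefrontal cortex 2 (Crabp2, adjusted p = 0.00589) and 1 without control prefrontal cortex 1 (the small nucleolar RNA Snord22). Snora30, Syne1 and Snord22 were named after their values were seen.

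Camera called 9 of 43 lists for the difference between regions, 8 with a positive median and 1 with a negative one. Pericyte genes (13 of 13 positive, 1 adjusted over the list alone, median 0.23) and extracellular matrix genes (20 of 23, 2 adjusted over the list alone, median 0.13, or 0.21 without irradiated hippocampus 3) were more positive in hippocampus, with camera adjusted p = 1.62e-05 and 2.6e-05 and an adjusted p = 0.219 with an estimated correlation for each. With a pseudocount of 0.1 the median of the pericyte genes was 0.38. Col1a1 and Fn1 are among the genes on both the extracellular matrix and the fibroblast list, so the results of these lists are not independent. Vtn, at 35.3 ± 4.1 against 34.7 ± 3.52 FPKM in prefrontal cortex, had a difference between regions of 0.65 ± 0.16. Endothelial genes were more positive in hippocampus too (18 of 24, 0 adjusted over the list alone and 6 at an unadjusted p under 0.05, median 0.20, camera adjusted p = 4.38e-05, adjusted p = 0.534 with an estimated correlation), with medians of 0.11 without irradiated hippocampus 2 and 0.06 without control hippocampus 1. With the mouse as a block 13 lists were called, the 9 and also astrocyte genes (camera adjusted p = 0.016), neurogenesis genes (0.037), olfactory bulb genes (0.039) and antigen presentation genes (0.017). With an estimated correlation and no block these 4 had adjusted p = 0.829, 0.292, 0.572 and 0.477, in the same order. Without irradiated hippocampus 2, 15 lists were called.

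**Figure D3:**
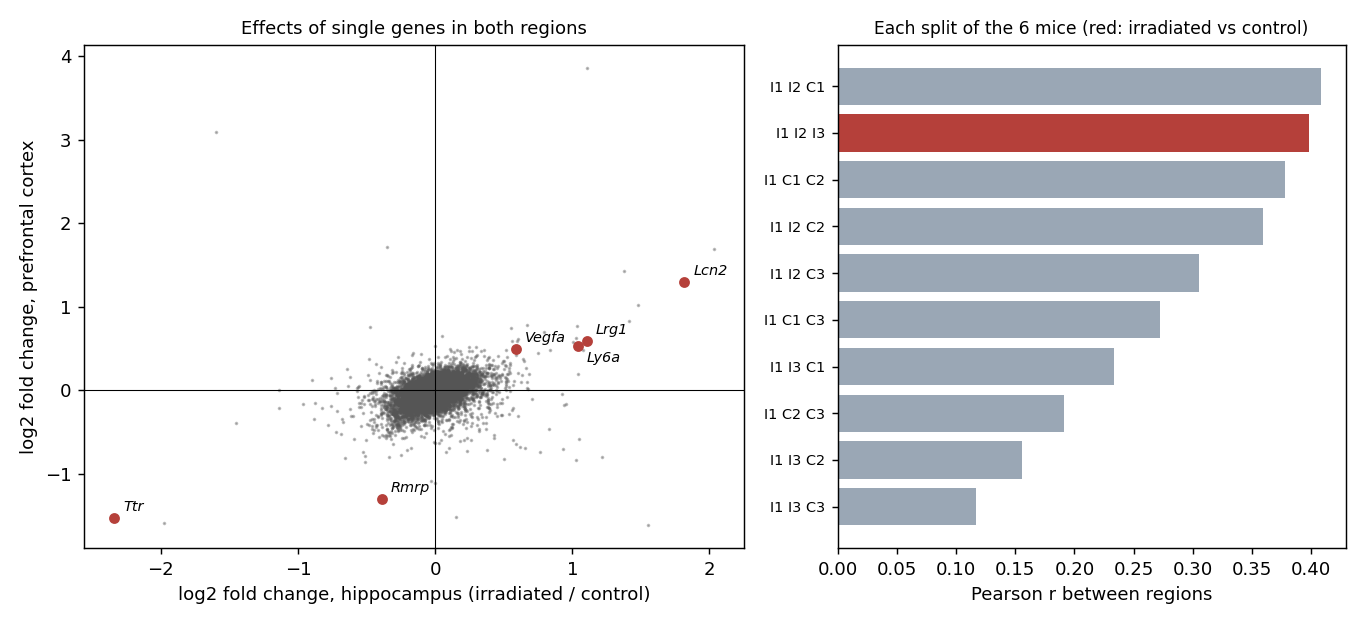
Left, log2 difference of irradiated minus control in hippocampus (x) and prefrontal cortex (y), 1 point per gene tested in both regions, with Vegfa, Lcn2, Lrg1, Ly6a, Rmrp and Ttr in red. Right, Pearson r across genes between the regions' differences for each of the 10 ways to split the 6 mice 3 against 3 (I, irradiated mouse; C, control mouse), where the real split (red bar) gave 0.398 and the highest other split 0.409.

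The effects of the 2 regions were then set against each other across 12456 genes tested in both. Pearson's r was 0.398 and Spearman's rho 0.447, across genes, which are not independent replicates. Among genes with an unadjusted p under 0.05 in both regions, 79 were higher in both (14.8 expected from independent lists), 125 lower in both (33.9 expected) and 14 opposite (46.2 expected). The r was 0.238 without irradiated prefrontal cortex 2 and 0.602 for genes of at least 10 FPKM in both regions. Because both regions come from the same mice, differences between animals enter both, and 1 of the 9 other splits of the mice gave an r of 0.409. That split still set 2 irradiated mice against 1, so its r holds part of any irradiation effect. In a fit of the mean over both regions of each mouse, added after the data were seen, limma called 1 of 12894 genes, Rmrp, with a log2 difference of -0.85 (adjusted p = 0.00614). In hippocampus Rmrp stood at 10.6 ± 2.8 against 14 ± 1.9 FPKM. In the same fit 1304 genes had an unadjusted p under 0.05, against 645 expected, and Vegfa had a log2 difference of 0.54 (adjusted p = 0.0905). The count of 1304 became 842 without irradiated mouse 2 and 1717 without irradiated mouse 3. Without irradiated mouse 1 and without irradiated mouse 3, 2 genes passed, and without control mouse 1, 3 genes, each time with Rmrp among them.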

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

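In this part, the tests of irradiated mouse 2, of endothelial cells and of the choroid plexus were chosen only after the result was seen.

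The irradiation effect on 9 gene lists differed between hippocampus and prefrontal cortex by camera's test of the difference, and none of the 9 passed with an estimated correlation (smallest adjusted p = 0.209). Medians of hippocampus minus prefrontal cortex, on the log2 scale, were 0.80 for meningeal and perivascular fibroblasts (0.43 in hippocampus, -0.48 in prefrontal cortex), 0.23 for pericytes (0.31 and 0.02) and 0.13 for extracellular matrix (0.03 and -0.10). They were 0.20 for endothelium (0.39 and 0.11), 0.26 for thalamus and habenula (0.08 and -0.13), 0.21 for reactive astrocytes (0.15 and -0.07) and 0.14 for cortical layers (0.13 and 0.08). For choroid plexus the median was -0.94 (-1.08 and -0.39), and for ribosomal proteins 0.0644 (-0.24 and -0.31). The fibroblast list holds markers of tissue that dissection can bring along, and a varying amount of it was not tested. Slc6a13, a member, was listed at 1.3, 1.83 and 4.03 FPKM in control hippocampus 1, 2 and 3. In irradiated hippocampus 1, 2 and 3 it was listed at 5.21, 5.39 and 4.71 FPKM. Without irradiated hippocampus 2 the median of the choroid plexus was 0.03 and the call was lost (camera adjusted p = 0.23). The ribosomal median turned without irradiated hippocampus 3 (-0.03), control hippocampus 3 (-0.01) and irradiated prefrontal cortex 2 (-0.05). Of 100 splits of the libraries within regions, 73 gave at least 9 lists (highest other 22), so chance is not excluded for these lists. The splits were drawn apart in each region although both regions come from the same mice. The 73 is therefore not a share of splits of the mice. For single genes the real split gave 0 and all 100 splits gave as many. The highest other, with 26 genes, set irradiated mice 1 and 2 with control 3 in hippocampus against the real grouping of prefrontal cortex in reverse, and so added regional differences in place of subtracting them. The same split without the reversal gave 0 genes.

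Ribosomal protein genes leaned lower in irradiated mice of both regions, with every irradiated library below every control library in prefrontal cortex but irradiated 3 within the control range in hippocampus. Fewer short transcripts in the irradiated libraries would lower other genes of the same length and level alike. In both regions the ribosomal median lay at percentile 0 of 10000 random lists matched on both, whose medians centred on -0.12 and -0.11. This cannot decide, because each gene's length was that of its longest annotated transcript. The random lists also held genes drawn apart, while ribosomal genes vary together (estimated correlation 0.89 in hippocampus and 0.84 in prefrontal cortex). Irradiated mouse 2 alone does not account for the difference, since without its libraries the medians were -0.15 in hippocampus and -0.18 in prefrontal cortex. Part of the difference went with length, as the medians were -0.11 and -0.19 with each library's length trend removed. What stays open is a loss of short transcripts and any difference between the animals or their handling that runs with treatment. A response to irradiation stays open too and was not tested apart from these.

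Acute-phase genes stood higher in every irradiated than in every control library of both regions, and endothelial markers in hippocampus only, with overlap in prefrontal cortex. A larger share of endothelial cells is not excluded, as the acute-phase level minus the endothelial marker level did not separate the groups (a gap between the lowest irradiated and the highest control library of -0.35 in hippocampus and -0.03 in prefrontal cortex, where a positive gap would part them). The mean difference of that level was -0.04 ± 0.12 (SE) in hippocampus, where acute-phase genes differed by 0.36 ± 0.09 and endothelial markers by 0.40 ± 0.15. In prefrontal cortex it was 0.12 ± 0.07, where acute-phase genes differed by 0.27 ± 0.04 and endothelial markers by 0.15 ± 0.09. The bound set for this cause, a mean difference of 0 or less in either region, was met in hippocampus, by less than the SE. More blood stays open, as does a response of the vessels to irradiation. The haemoglobin genes Hbb-b1, Hba-a1 and Hba-a2 differed by 0.0517 ± 0.448 in hippocampus and 0.85 ± 0.50 in prefrontal cortex, a spread too wide to decide. That mean rests largely on Hba-a2, which jumped between libraries. It was listed at 14.6, 0.0137 and 0.0139 FPKM in irradiated and 14.7, 26.9 and 0.0143 FPKM in control hippocampus. In prefrontal cortex Hba-a2 stood at 18.2 ± 20 against 0.0138 ± 0.00017 FPKM, and Hba-a1 at 40.5 ± 26.8 against 55.9 ± 10.4 FPKM. The mean of the 3 is therefore a poor measure of blood. Among blood genes chosen after their values were seen, every irradiated library lay above every control library in hippocampus for Hbb-b1 (139.9 ± 41.6 against 93.6 ± 4.15 FPKM), Hbb-b2 (28.3 ± 7.04 against 18.2 ± 2.54) and Alas2 (2.2 ± 0.537 against 1.04 ± 0.1), and the groups overlapped for all 3 in prefrontal cortex.

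Choroid plexus transcripts were nearly absent from irradiated hippocampus 2, at a median of 4.60% of the other 5 hippocampus libraries over 19 markers. Cortical or striatal tissue mixed into the sample is argued against, since 189 genes higher in control prefrontal cortex put its share at 6.92%, within the -2.92% to 7.42% of the other hippocampus libraries. Choroid plexus left out at dissection may be the cause, because the markers were low together, with an SD of 0.99 of their log2 ratios, close to the bound of 1 set for it. No biological explanation was tested for a single library.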

How the results depend on the processing

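In this part, the pseudocounts of 0.1 and 0.5, the removal of the transcript length trend (alone or with the block) and the mean effect per mouse with its left-out mice were chosen only after the data were seen. The rescalings, low-value filters and robust moderation were planned for counts, and only their form for FPKM was set afterwards. Over 166 results for named genes and 3115 alternatives, 3095 kept their direction and their side of the threshold, 11 passed it in addition, 1 no longer passed (Snora81 in 1 fit over all 12 libraries) and 8 reversed. Where a value changed, the cause was not tested.

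For genes in hippocampus (0 called), equal totals gave 4, a threshold of 0.10 gave 3, an unadjusted p under 0.05 with 1.5-fold gave 57, robust moderation gave 3 and 1 fit over all 12 libraries gave 1, and leaving out a library gave 0 to 1. In prefrontal cortex (1 called) no filter on low values gave 2, a threshold of 0.10 gave 5, unadjusted p with 1.5-fold gave 49, 1 fit over all 12 libraries gave 0 and leaving out a library gave 1 to 4. For the difference between regions (0 called) no filter gave 1, unadjusted p with 1.5-fold gave 80 and leaving out a library gave 0 to 2. Between the regions of control mice (3922 called) unadjusted p with 1.5-fold gave 1495, of which 1477 were among the 3922. The mean effect per mouse gave 1 to 3 genes when a mouse was left out. For gene lists in hippocampus, prefrontal cortex and their difference, an estimated correlation gave 0, 0 and 0 and fry's directional test 0, 0 and 0. Leaving out a library gave 16 to 28 lists in prefrontal cortex and 9 to 15 for the difference. The correlation of effects across regions was 0.602 for genes of at least 10 FPKM and 0.238 to 0.458 when a library was left out.

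Directions that reversed belonged to genes that had not passed. In hippocampus, removing the length trend gave 0.0135 for Tyrobp and -0.019 for Dcx, and Fos ran from -0.036 to 0.29 when a library was left out. In prefrontal cortex, Aif1 was 0.0313 with equal totals, 0.12 without the length trend and -0.15 to 0.0511 when a library was left out, Dcx was 0.0146 with equal totals, and Ttr ran from -2.59 to 0.0311 when a library was left out.

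The mouse as a block gave 0 genes for the difference between regions and 4326 between regions in control mice (4331 with the length trend removed), and 13 lists for the difference. Within a region, irradiated and control mice share only a number, with correlations of 0.10, -0.02 and -0.16 in hippocampus and 0.14, 0.12 and 0.12 in prefrontal cortex. A block on that number gave 0 genes and 25 lists in hippocampus, with the antioxidant list lost, and 1 gene and 27 lists in prefrontal cortex, with glutamate receptor and histone lists gained. The block changed no other call.

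DESeq2 and limma-voom were planned for counts and not run, since the values are normalized. Estimated depth was similar in all groups and gives no counting error per gene.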

Other observations

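In this part, the fit of the mean effect per mouse was chosen only after the result was seen.

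A list of transport genes, with carriers and enzymes of retinoic acid among them, leaned lower in prefrontal cortex. There 11 of 16 genes of thyroid, retinoid and steroid transport had negative differences, 4 lower adjusted over the list alone and 0 over all genes in limma (6 lower and 1 higher at an unadjusted p under 0.05, median -0.08, mean -0.24, camera adjusted p = 0.0366, adjusted p = 0.329 with an estimated correlation). Crabp1, a carrier of retinoic acid, stood at 1.77 ± 0.586 against 3.53 ± 0.989 FPKM and Aldh1a2, which makes retinoic acid, at 1.75 ± 0.743 against 3.33 ± 0.126 FPKM. Aldh1a2 is also a member of the fibroblast list, which leaned lower in prefrontal cortex too. The 2 list results are therefore not independent, and retinoic acid genes were not tested as a list of their own. In hippocampus the list was not called (10 of 16 negative, median -0.09, camera adjusted p = 0.938), nor was the difference between regions (camera adjusted p = 0.294). Crabp1 stood at 0.905 ± 0.247 against 1.06 ± 0.213 FPKM there, and Aldh1a2 was listed at 5.61, 5.06 and 5.89 FPKM in irradiated and 1.9, 2.6 and 5.75 FPKM in control mice. The call in prefrontal cortex was lost without control 1 (median -0.02, camera adjusted p = 0.13), control 3 (camera adjusted p = 0.0566) or irradiated 1 (0.0634), in 1 fit over all 12 libraries (0.0746), with no filter on low values (0.0561) and with the length trend removed (0.0678), and the median was -0.12 without irradiated 2 and -0.01 with equal totals.

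Chance was examined with other splits of the samples. With 3 against 3 the 10 splits are too few for a share under 0.05. In hippocampus the real split gave 0 genes (highest other 1, 10 of 10 splits as many) and 26 lists (highest other 17, 1 of 10). In prefrontal cortex it gave 1 gene (highest other 3, 5 of 10) and 25 lists (highest other 17, 1 of 10). Hippocampus against prefrontal cortex in control mice gave 3922 genes (highest other 1, 1 of 10), and the mean effect per mouse gave 1 gene (highest other 2, 3 of 10).

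The correlation of effects across regions, 0.398, was reached by 4 of 100 pairs of splits drawn apart in each region (highest other 0.465). Such draws ignore that both regions come from the same mice, so they exclude no chance difference between the animals. With the same split of the 6 mice in both regions, 2 of 10 gave as large an r, the highest other being 0.409 for irradiated mice 1 and 2 with control mouse 1. By covariance the real split was the highest of the 10, at 0.0093 against 0.00675 for the highest other. Every other split still sets 2 irradiated mice against 1, so its r holds part of any irradiation effect. The splits therefore cannot show what r animals give without irradiation. Differences between the animals stay open as a cause, as 10 splits are also too few for a share under 0.05.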
